A study of Homo sapiens with 4 samples.

How the data were processed

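RNA was measured in single cells of MCF7 strain AA, a strain of an established human breast cancer cell line that expresses the estrogen receptor. Cells were exposed to 500 nM bortezomib, an inhibitor of the proteasome, and harvested before treatment (0 h), after 12 h, after 48 h, or after 72 h followed by drug wash and 24 h of recovery (called recovery). Libraries were made with the Chromium Single Cell 3′ kit of 10x Genomics, which counts the 3′ ends of polyadenylated RNA. There was 1 library per time point, so groups held 1 sample each. The labels of the individual library give 48 h for the t48 library, whereas the treatment and design texts give 24 h for it. It was grouped as 48 h here, and its true time is not settled by the data. Column names tied every cell to a library, and the names of the 12 h cells lack the 7 of MCF7 that the other names carry.

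The deposited table holds raw counts of unique molecular identifiers (UMIs) per gene and cell, without normalization. Cell Ranger 2.1.0 and the genome build GRCh38 are named in the submitters' processing notes, without a statement of what each was used for. The gene annotation and the cell filters of the authors are not given in the sources used here. All values were whole numbers, and each of the 20039 genes had a count in at least 3 cells. The table held 7555 cells of 4 libraries, and 29 barcodes occurred in 2 libraries. Gene positions and mRNA lengths were taken from GENCODE release 29 on GRCh38, which holds 15942 of the 20039 symbols.

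Counts were summed over all deposited cells of a library and expressed per 1000000 UMIs of the library (CPM). Library totals ranged from 35173024 to 52689722 UMIs, so 3 UMIs, the floor used for a count of 0, corresponded to 0.0569 to 0.0853 CPM. CPM values carry exact 95% Poisson intervals, folds carry exact conditional 95% intervals of a ratio of 2 counts, and shares carry exact Clopper-Pearson 95% intervals. These intervals and floors cover counting error only. With 1 library per time point, no test between time points was run and no p-value or standard error is given. Comparisons were 12 h, 48 h and recovery each against 0 h, 48 h against 12 h, and recovery against 48 h. A gene counted as higher or lower by a rule of size: at least 10 CPM in at least 1 of the 2 libraries, at least 2-fold with 0.5 UMI added to each sum, and a 95% interval of the fold that excludes 1. That rule describes these libraries and does not show that another culture would give the same genes.

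The choices in this paragraph, except those in its last sentence, were made before the data were examined. 29 gene lists were described by the median log2 fold of the members with at least 10 CPM in either library, where at least 5 members passed. Each median was placed among 10000 random lists of the same size, matched on mean expression in 20 bins, and is called above or below when it lies outside the central 95% of them. This range need not be centred on no change, so a median inside it can still be far from no change. Named genes were the 10 highest and the 10 lowest by log2 fold among genes that met the rule of size with at least 50 CPM in the higher library, for the comparisons against 0 h and for recovery against 48 h. Up to 4 members of each list with the largest absolute log2 fold and a fixed panel of 25 genes were also named. Alternatives were median-ratio size factors of the DESeq2 type, TMM of edgeR 4.0.16, a total without mitochondrially encoded and ribosomal protein genes, equal weight per cell, other CPM minimums, 5 UMIs added, 1.5-fold and 4-fold limits, filtered cells, cells without the top 5% by UMIs, cells called G1, and libraries thinned to the smallest total. No doublet caller was run, because all cells come from 1 cell line, and the alternative without the top 5% of cells stands in its place. Alternatives written for normalized values and for cells without a library name did not apply. A further filter, cells with at least 10000 UMIs and 2% to 20% mitochondrial UMIs, a restriction to genes with mRNAs of 800 to 2000 nt, the distribution of the interferon list over cells, and clusters of cells thinned to 1 depth were added after the data were seen.

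For values per cell, each cell was thinned to 6000 UMIs, and 38 cells at 0 h and 273 cells at 12 h with fewer UMIs were left out. Cell cycle phases were called from scores of the S and G2/M lists in scanpy 1.11.5. All cells were clustered together on log-normalized values, with 2000 highly variable genes, 30 principal components, 15 neighbours and Leiden resolution 0.5. Distances between cells were 1 minus the Pearson correlation over 2000 genes in 300 cells drawn per library. The work used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, igraph 0.11.9, sklearn 1.9.0 and R 4.3.3.

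The rule of size was tested on simulated data drawn at the depths of these libraries. Genes simulated at 3-fold or 4-fold were found in 98.4% to 100% of cases, and genes simulated at 1.5-fold or with no change were called in 0%. The 95% intervals held the true fold for 94.7% to 95.2% of simulated genes. Between 3% and 9% of simulated lists without a change fell outside the central 95%. Intervals of real genes between cultures would be wider, since the simulation holds counting error alone.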

Results

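Single-cell RNA counts were collected from MCF7 strain AA cells at 4 time points of exposure to bortezomib, 1 library each, without replicates. The 0 h library held 1726 cells and 37738553 UMIs, the 12 h library 2743 cells and 42208508 UMIs, the 48 h library 1851 cells and 52689722 UMIs, and the recovery library 1235 cells and 35173024 UMIs. Median UMIs per cell were 20570.5, 14958, 25271 and 25859 in that order, and median genes per cell were 4030, 3487, 4102 and 4069. The median share of UMIs from mitochondrially encoded genes was 7.65% at 0 h, 5.57% at 12 h, 3.55% at 48 h and 3.51% at recovery. Cells with under 1% of mitochondrial UMIs made up 0.811%, 1.46%, 1.67% and 13.9% of the libraries. The median share from ribosomal protein genes was 36.2%, 32.1%, 35.1% and 28.8%.

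The comparison of 12 h with 0 h asks what the cells express early under proteasome inhibition. After 12 h, 31 of 33 subunits of the proteasome, 23 of 25 cytosolic heat shock chaperones and 23 of 28 genes of the integrated stress response were higher. Lower were 24 of 37 genes of the S phase, 30 of 44 of the G2/M phases and 13 of 23 targets of the estrogen receptor. HSPA1A (chromosome 6, 31815464 to 31817946), an inducible HSP70 chaperone, had 58.9 CPM (95% interval 56.5 to 61.4) at 0 h and 1425 CPM (1413 to 1436) at 12 h, a log2 fold of 4.60 (4.54 to 4.66). PSMD6, a subunit of the regulatory cap of the proteasome, was higher, from 469 to 2954 CPM. MKI67 (chromosome 10, 128096659 to 128126385), a marker of dividing cells, had 85.5 CPM (95% interval 82.5 to 88.5) at 0 h and 16.4 CPM (15.2 to 17.7) at 12 h, a log2 fold of -2.38 (-2.50 to -2.26). By the rule of size, 1074 genes were higher and 1100 lower among 7860 with enough expression, and the median log2 fold of all of them was 0.07.

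The proteasome list held 31 of 33 members higher and none lower, with a median log2 fold of 1.88 against a central range of -0.17 to 0.53 for matched random lists. PSMC4 (log2 fold 2.52), PSMD13 (2.33) and PSMA5 (2.23) were among its highest members. In the panel, PSMD12 went from 85.4 to 362 CPM and PSMB5 from 252 to 672 CPM. Proteasome assembly and regulation genes had a median of 0.54, inside the range, with 5 of 19 members higher, among them NGLY1 (1.46), USP14 (1.42) and the assembly chaperone POMP (1.35). Among cytosolic heat shock chaperones, 23 of 25 were higher, with a median of 2.35. HSPA6 (chromosome 1, 161524540 to 161526910) had the largest log2 fold among genes with at least 50 CPM at 0 h or 12 h, 8.13, from 0.371 to 108 CPM. HSPB8 (4.77), HSPA1B (4.82), BAG3 (3.97) and DNAJB1 (3.34) were higher as well. HSPA1A and HSPA1B, and HSPA6 and its close relative HSPA7, are so alike that counts of one may include reads of the other.

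Genes of the integrated stress response, which ATF4 and CHOP drive, were higher for 23 of 28 members, with a median of 1.92. DDIT3, which encodes CHOP (chromosome 12, 57516588 to 57521737), had 16.1 CPM (95% interval 14.8 to 17.4) at 0 h and 321 CPM (316 to 326) at 12 h, a log2 fold of 4.32 (4.20 to 4.44). ATF3 (4.62), the cystine transporter SLC7A11 (4.61) and CHAC1 (4.56) were higher too. The list of the unfolded protein response and endoplasmic reticulum chaperones had a median of 0.38, inside the range, with 4 of 20 members higher: HERPUD1 (2.01), HSPA5 (1.69), DNAJB11 (1.59) and DNAJB9 (1.54). NRF2 targets of the oxidative stress response had 10 of 19 members higher and a median of 1.03, above the range, with HMOX1 at 3.32, OSGIN1 at 3.29 and AKR1C1 at 2.25. Autophagy and ubiquitin genes had a median of 0.78, above the range, and 8 of 18 were higher, including GABARAPL1 (5.15), ZFAND2A (4.17), the polyubiquitin gene UBC (3.70) and MAP1LC3B (2.46). SQSTM1, an autophagy receptor, had a log2 fold of 1.95.

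Targets of p53 were higher for 11 of 20 members (median 1.19, above the range), among them GADD45A (3.80), GDF15 (3.62), SESN2 (2.75) and the cell cycle inhibitor CDKN1A (2.01). GDF15 and SESN2 are in the integrated stress response list too, and other lists also share members, so the lists are not independent. Apoptosis regulators had a median of 0.47, inside the range, with BBC3 (2.32), PMAIP1 (1.96) and CASP3 (1.37) higher and BIRC5 (-1.97) lower. MCL1 had 96.1 to 133 CPM, within 2-fold. Immediate early genes had 9 of 16 members higher and a median of 1.18, above the range, with FOSL1 (5.59), JUN (2.75) and MYC (2.11) higher. Outside these lists, the highest of the genes with at least 50 CPM in either library were PGF (7.03), MLLT11 (5.02), the glutathione peroxidase GPX3 (4.61) and MAP1B (4.44).

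S phase genes were lower for 24 of 37 members (median -1.56), and G2/M genes for 30 of 44 (median -1.62), both below the range, with 2 G2/M members higher. In cells called G1 alone, a selection against cells high in these lists, the medians were 0.036 and 0.39, that of the list of cyclins, kinases and inhibitors of G1 was 0.13, and MKI67 was at 0.011. UHRF1 (-3.59), CDCA7 (-3.35) and WDR76 (-3.12) were the lowest S phase members, and TOP2A (-3.57), DLGAP5 (-3.34) and PSRC1 (-3.14) the lowest G2/M members. Cyclins, kinases and inhibitors of G1 had a median of -1.21, below the range but inside it with median-ratio or TMM scaling or equal weight per cell, with E2F2 (-3.32), E2F1 (-2.59), CCNE2 (-2.25), CDK2 (-2.24) and CCND1 (-1.74) lower. Histones, a family of near-identical genes, were lower for 10 of 16 members (median -1.52), including HIST1H2BD (-2.95) and H2AFZ (-1.84). Estrogen receptor targets were lower for 13 of 23 members (median -1.28), including AGR3 (-3.77), GREB1 (-2.34) and AGR2 (-2.27). The receptor gene ESR1 (chromosome 6, 151656691 to 152129619) went from 85.7 to 23.7 CPM and PGR, the progesterone receptor, from 15.8 to 2.99 CPM. TFF1 (4694 to 2824 CPM) and XBP1 (774 to 523 CPM) stayed within 2-fold. Luminal epithelial markers had a median of -0.56, below the range, with MUC1 (-3.29) and GATA3 (-2.09) lower and KRT8 (3058 to 3099 CPM) and KRT18 (3748 to 6526 CPM) within 2-fold. KRT8 and KRT18 overlap on opposite strands of the annotation.

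Interferon response genes were lower for 8 of 15 members (median -1.08, below the range), including OAS3 (-3.42), OASL (-3.20), IRF9 (-2.92) and ISG15 (-2.20), and 3 were higher, while OASL was at 0.18 in cells called G1 alone. The list's median share of a thinned cell's UMIs was 0.05% at 0 h and 0.05% at 12 h. Nuclear-encoded oxidative phosphorylation genes were below the range with a median of -0.40, and 5 of 34 were lower, among them ATP5I (-1.81) and NDUFB1 (-1.64). Mitochondrially encoded genes (-0.41), cytosolic ribosomal proteins (-0.18), ribosome biogenesis and MYC targets (0.53), glycolysis and hypoxia genes (0.17), cholesterol synthesis genes (-0.18), NF-kB targets (0.06) and the cytoskeleton (-0.22) had medians inside the range. In the last list TMSB10 (-3.46) and TMSB4X (-2.85), which bind actin monomers, were lower and TUBA4A (5.05) was higher. The other lowest of the genes with at least 50 CPM in either library were the noncoding LINC00052 (-4.43), ADCY1 (-3.87), SAMD1 (-3.81), IGFBP5 (-3.55), CALML5 (-3.52), IRX3 (-3.00), CTXN1 (-2.90), SLC2A4RG (-2.90) and EEF1A2 (-2.86). The metallothioneins MT2A (-2.59), MT1F (-2.0) and MT1X (-1.38) were lower. TMM scaling moved the median log2 fold of all genes by 0.13 and gave 1354 higher and 820 lower genes. A total without mitochondrially encoded and ribosomal protein genes moved it by -0.15 and gave 833 and 1437.

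**Figure D1:**
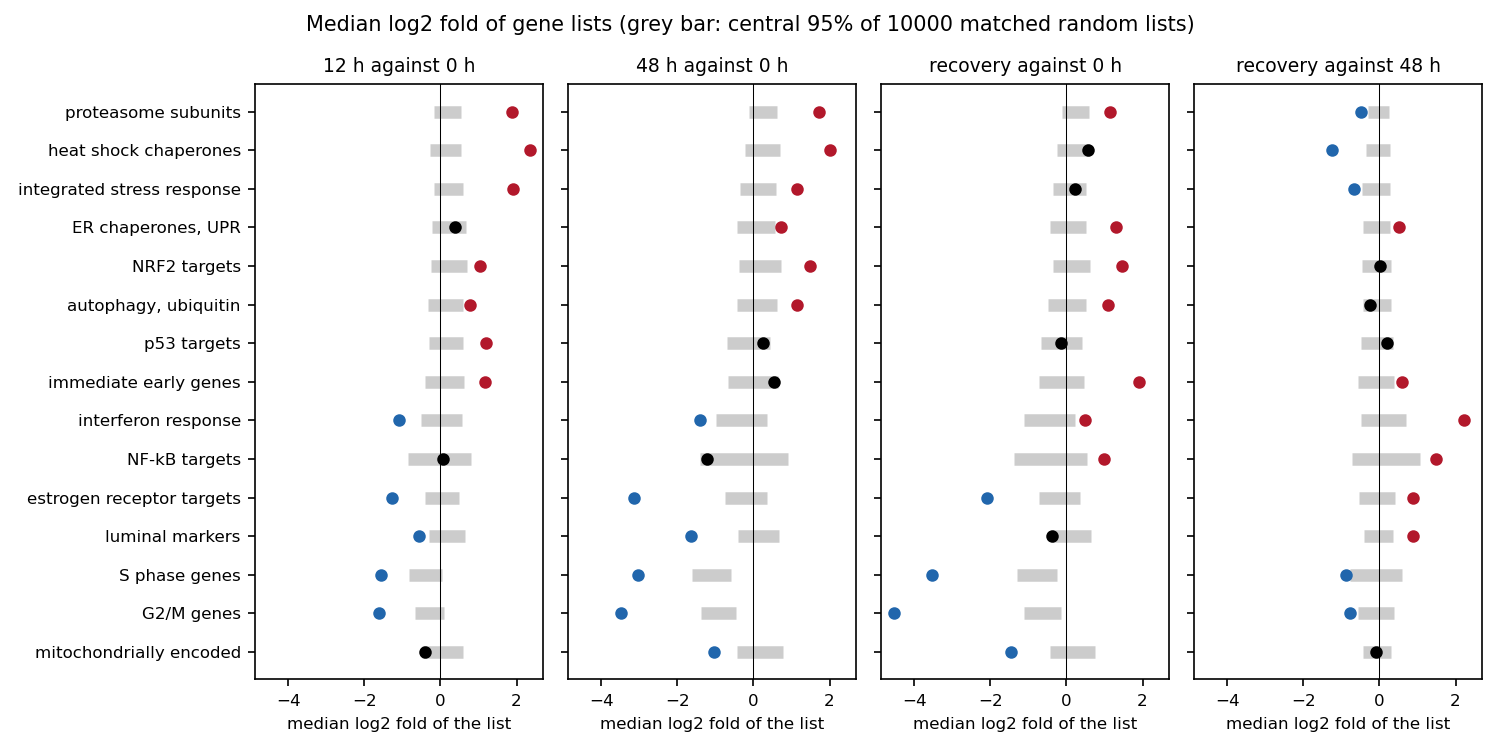
Median log2 fold of 15 of the fixed gene lists (horizontal axis) in 4 comparisons, as points, with the central 95% of 10000 matched random lists as grey bars, and points above the bar in red, below it in blue and inside it in black. The proteasome list has medians of 1.88, 1.72 and 1.14 in the comparisons with 0 h, and the G2/M list -1.62, -3.49 and -4.52.

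The comparison of 48 h with 0 h asks which changes are present after longer exposure. At 48 h too, 28 of 33 proteasome subunits and 19 of 23 heat shock chaperones were higher. So were 11 of 19 NRF2 targets, with 8 within 2-fold, and the median of that list for 48 h against 12 h, -0.07, lay inside the range. ESR1 had 85.7 CPM (95% interval 82.8 to 88.7) at 0 h and 1.69 CPM (1.36 to 2.08) at 48 h, a log2 fold of -5.66 (-5.99 to -5.36), and 20 of 23 estrogen receptor targets were lower. Genes of the cell cycle were lower for 34 of 36 members of the S phase list and 38 of 44 of the G2/M list, while in cells called G1 alone both medians lay inside the range. By the rule of size 1034 genes were higher and 2082 lower among 7737, and the median log2 fold of all of them was -0.23.

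Of the proteasome subunits, 28 of 33 were higher (median 1.72), with PSMD6 at 2.95, PSMC4 at 2.91, PSMB3 at 2.79 and PSMB7 at 2.67. POMP was higher (1.98) and DDI2, a protease that activates the transcription factor NFE2L1, lower (-1.50), while the assembly and regulation list had a median of -0.14, inside the range. Heat shock chaperones were higher for 19 of 23 members (median 2.0), including HSPA6 (7.46), HSPB8 (4.33), HSPA1B (4.11) and HSPA1A (3.98). The integrated stress response list had 14 of 25 members higher and 3 lower (median 1.15, above the range), with ATF3 at 4.97, DDIT3 at 3.80 and PPP1R15A at 3.54. NRF2 targets were higher for 11 of 19 members (median 1.49, above the range). AKR1C1, an aldo-keto reductase whose reads are hard to tell from those of AKR1C2, had a log2 fold of 6.58. The unfolded protein response list reached a median of 0.73, above the range, with DNAJB9 (2.56), HERPUD1 (2.19) and HSPA5 (1.84) higher. XBP1 (chromosome 22, 28794555 to 28800597), a transcription factor of that response, was lower, with 774 CPM (95% interval 765 to 783) at 0 h and 87.8 CPM (85.3 to 90.4) at 48 h, a log2 fold of -3.14 (-3.19 to -3.10). Autophagy and ubiquitin genes had 11 of 19 members higher (median 1.16, above the range), including GABARAPL1 (5.82), ZFAND2A (4.44) and MAP1LC3B (3.60).

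The lowest estrogen receptor targets were MYB (-7.82), AGR3 (-7.27) and TFF3 (-6.61), and the list's median was -3.14. TFF1, at 4694 to 5523 CPM, stayed within 2-fold. Luminal markers had 11 of 19 members lower (median -1.65, below the range), including SPDEF (-3.77), GATA3 (-3.29), KRT19 (-2.84) and KRT8 (-1.45), whereas KRT18 was within 2-fold (-0.14). Basal and mesenchymal markers went both ways: KRT6A was higher (6.71) and FN1 (-3.86), CAV1 (-3.53) and KRT17 (-2.04) were lower, for a median of -2.04 inside the range. S phase genes had a median of -3.03 and G2/M genes of -3.49, with UHRF1 (-6.59), HELLS (-5.39), BRIP1 (-5.49), CENPA (-7.12), TOP2A (-6.30) and BIRC5 (-6.16) among the lowest. In cells called G1 alone, a selection against cells high in these lists, the medians were -0.40 and -0.18, inside the range. KIAA0101, which encodes a partner of the replication clamp, was lower (-5.60). The G1 list had a median of -1.34, with E2F2 (-7.77), E2F1 (-3.89) and CCND1 (-3.63) lower. This was inside the range, which was itself wholly negative, at -1.82 to -0.0055. Histones had 14 of 16 members lower (median -2.27, below the range), with HIST1H4C at -2.81 and H2AFJ at -2.98.

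Mitochondrially encoded genes were lower for 7 of 13 members (median -1.04, below the range), including MT-ND2 (-1.53) and MT-CYB (-1.30), though inside the range of lists not matched on expression. Nuclear-encoded oxidative phosphorylation genes had a median of -0.01, inside the range, with NDUFB9 (1.70) and NDUFA4 (1.44) higher. Interferon genes were lower for 9 of 16 members and higher for 4 (median -1.40, below the range), with IFI6 (-5.53) and OAS3 (-5.01) lowest. The summed level of the list was 919 CPM at 0 h and 769 CPM at 48 h. Its median share of a thinned cell's UMIs was not lower, at 0.05% at 0 h and 0.0667% at 48 h. Targets of p53 had a median of 0.26, inside the range, although GADD45A (3.73) and GDF15 (3.07) were higher, and CDKN1A was within 2-fold (0.97). Medians inside the range were also found for apoptosis regulators (0.51), immediate early genes (0.54), NF-kB targets (-1.21), glycolysis and hypoxia (0.16), cholesterol synthesis (-0.39), ribosome biogenesis and MYC targets (-0.03) and the cytoskeleton (-0.01). Within these lists CASP7 (1.79), FOSL1 (5.89), KLF6 (3.45), BNIP3L (2.0), the glycolytic enzyme gene GAPDH (1.72) and TUBB2A (3.28) were higher, and EGR3 (-6.86), REL (-2.23), TM7SF2 (-2.96), CAD (-3.70) and STMN1 (-3.64) were lower. Cytosolic ribosomal proteins had a median of -0.06, below the range, which was 0.44 with median-ratio scaling and 0.43 with TMM, so its sign depended on the scaling, and it was inside the range of lists not matched on expression. Among genes with at least 50 CPM in either library, the highest were MLLT11 (7.51), HSPA6, TUBA4A (7.01), AKR1C1, FOSL1, GPX3 (5.87), GABARAPL1, MAP1B (4.95), the keratin gene KRT81 (4.53), which has close relatives, and ZFAND2A. CALML5 (-9.52), IGFBP5 (-8.97), RP11-662G23.1 (-7.42) and LINC00052 (-7.31) were the lowest of them. MT2A (-3.49), MT1F (-3.02) and MT1X (-1.90) were lower. Median-ratio scaling moved the median log2 fold of all genes by 0.50 and gave 2069 higher and 1104 lower genes, and TMM moved it by 0.49 and gave 2051 and 1127. A total without mitochondrially encoded and ribosomal protein genes moved it by -0.13, with 883 higher and 2468 lower.

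Between 12 h and 48 h, the question is what changed under continued exposure. Estrogen receptor targets (-2.05), S phase (-1.19), G2/M (-1.41), integrated stress response (-1.07) and p53 genes (-0.77) had medians below the range, and 13 of 20 estrogen receptor targets were lower. In cells called G1 alone the S phase median was -0.39, inside the range. DDIT3 was at 321 CPM at 12 h and 224 CPM at 48 h, and CCND1 at 113 and 30.3 CPM. Proteasome subunits had a median of -0.05, inside the range, with 1 of 33 lower. By the rule of size 226 genes were higher and 991 lower among 7065, with a median log2 fold of -0.28.

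Also below the range at 48 h were luminal markers (-0.90), histones (-0.91), heat shock chaperones (-0.52, with 4 of 25 lower), mitochondrially encoded genes (-0.63) and ribosome biogenesis and MYC targets (-0.65). Against random lists not matched on expression, the heat shock and the mitochondrially encoded medians were inside the range. Above it were nuclear-encoded oxidative phosphorylation (0.54), the cytoskeleton (0.53) and the unfolded protein response (0.30), with 2 of 34, 4 of 19 and 1 of 22 members higher. NRF2 targets (-0.07), autophagy (0.16), apoptosis (-0.53), immediate early (-0.06), interferon (-0.13), NF-kB (-0.74), G1 (-0.61), glycolysis (0.06), cholesterol (-0.06), proteasome assembly (-0.47) and ribosomal protein genes (0.14) were inside it. Median-ratio scaling moved the median log2 fold of all genes by 0.42 and gave 711 higher and 342 lower genes, and TMM moved it by 0.36 and gave 616 and 404.

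**Figure D2:**
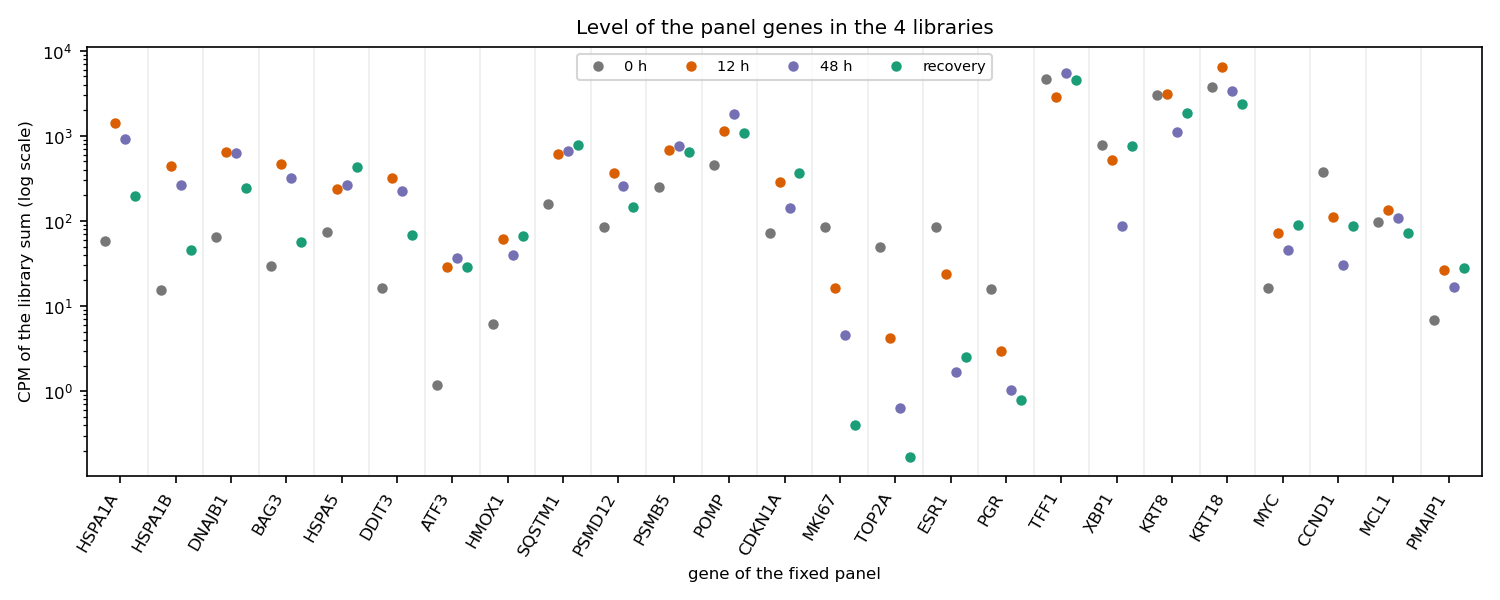
Level of the 25 genes of the fixed panel in CPM (vertical axis, log scale) in the 4 libraries, 1 point per library and gene. HSPA1A is at 58.9, 1425, 929 and 195 CPM from 0 h to recovery, and TOP2A at 49.9, 4.19, 0.626 and 0.171 CPM.

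The comparison of recovery with 0 h asks how far expression 24 h after the drug was washed out resembled that of untreated cells. Untreated cells were sampled only at 0 h, so drug and time in culture cannot be told apart. Nor can a change within cells be told from a change in which cells were left. Genes of the cell cycle were lower for 34 of 36 S phase and 40 of 44 G2/M members, and estrogen receptor targets for 16 of 23. MKI67 had 85.5 CPM (95% interval 82.5 to 88.5) at 0 h and 0.398 CPM (0.218 to 0.668) at recovery, a log2 fold of -7.70 (-8.62 to -7.00). Of the list of the unfolded protein response and endoplasmic reticulum chaperones, 13 of 22 members were higher and 9 within 2-fold. HSPA5 (chromosome 9, 125234853 to 125241330), which encodes BiP, had 73.4 CPM (95% interval 70.7 to 76.2) at 0 h and 432 CPM (425 to 439) at recovery, a log2 fold of 2.56 (2.50 to 2.62). Proteasome subunits were higher for 24 of 33 members (median 1.14), while the heat shock list lay inside the range at 0.55, although above it against random lists not matched on expression and, at 0.82, in cells called G1 alone. By the rule of size 942 genes were higher and 2067 lower among 7790, and the median log2 fold of all of them was -0.26.

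The unfolded protein response list had 13 of 22 members higher (median 1.30, above the range), including DNAJB9 (3.36), HERPUD1 (2.35) and MANF (2.04), and XBP1 was at -0.01. NRF2 targets were higher for 14 of 19 members (median 1.47, above the range), with HMOX1 at 3.42 and the ferritin light chain gene FTL at 2.93. The ferritin heavy chain gene FTH1 was at 13434 CPM at 0 h and 58603 CPM at recovery, and its pseudogenes may share reads with it. Autophagy and ubiquitin genes were higher for 11 of 20 members (median 1.10, above the range), including GABARAPL1 (4.34), OPTN (3.62) and UBC (3.25). Immediate early genes were higher for 11 of 16 members (median 1.90, above the range), with ATF3 (4.62), the phosphatase DUSP1 (3.82) and FOSL1 (3.61) higher and EGR3 (-6.28) lower. Among heat shock chaperones 7 of 23 were higher, with CRYAB (6.95), HSPB8 (5.48), DNAJB1 (1.91) and HSPA1A (1.73) first. Of the proteasome list, PSMC4 (2.39), PSMB7 (2.17) and PSMB3 (2.07) were the highest. The assembly list had a median of 0.00, inside the range, with POMP at 1.25 and DDI2 at -1.52. The integrated stress response list had a median of 0.24, inside the range, with GDF15 (4.32) and SLC7A11 (2.78) higher and PHGDH, an enzyme of serine synthesis, lower (-4.16).

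Interferon response genes went both ways, 10 of 20 higher and 4 lower (median 0.50, above the range). ISG15 (2.71) and IFI44 (6.76) were higher, and IFI6 (-5.14) and OAS3 (-2.80) lower. That median was -0.090 in cells with at least 10000 UMIs and 2% to 20% mitochondrial UMIs, a filter that also changes which members pass the expression minimum. NF-kB targets and cytokines had 3 of 8 members higher and 2 lower (median 0.98, above the range). CXCL8, an interleukin that attracts neutrophils, went from 0.0265 to 12.3 CPM (1 UMI at 0 h, log2 fold 8.27), IL6 from 0.132 to 41.0 CPM and RELB from 2.73 to 19.2 CPM. In cells thinned to 6000 UMIs, 14.9% of recovery cells (12.96% to 17.0%) held an IL6 UMI, while 0 of 1688 cells did at 0 h, which at that depth allows up to 0.218% of cells with a UMI. Detection depends on depth, and 0.0579% of unthinned cells held one at 0 h and 36.3% at recovery. FGB (chromosome 4, 154562956 to 154571086), which encodes a fibrinogen chain, had 0 UMIs at 0 h and 84.2 CPM at recovery, at least 1059-fold higher against a floor of 3 UMIs in the 0 h library, with a lower 95% limit of 9.75 for the log2 fold. Its UMIs were found in 24.5% of thinned recovery cells (22.2% to 27.0%) and in 6.05% at 48 h (5.01% to 7.24%).

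Estrogen receptor targets had a median of -2.09, below the range, with AGR3 (-6.56), MYB (-6.29), TFF3 (-5.55) and RET (-5.41) lowest. ESR1 was at -5.07 and PGR at -4.29, while TFF1 was at -0.06. Luminal markers had a median of -0.37, inside the range, with GATA3 (-2.50) and SPDEF (-1.61) lower and the tight junction gene CLDN4 higher (1.72). S phase genes had a median of -3.53 and G2/M genes of -4.52, below the range. RRM2 (-6.99), HELLS (-6.53), TOP2A (-8.08) and BIRC5 (-7.66) were among the lowest, and WDR76 had 0 UMIs, at least 163-fold lower against a floor of 3 UMIs. That S phase median was -3.53 also with WDR76 set at this bound. The G1 list had a median of -0.86, inside the range, with E2F1 (-5.15) and CCND1 (-2.09) lower and CDKN1A (2.36) and MYC (2.43) higher. Histones had a median of -0.27, inside the range, and HIST1H4C was lower (-5.53). Mitochondrially encoded genes were lower for 9 of 13 members (median -1.44, below the range), and MT-CO3 was at -1.67. Cytosolic ribosomal proteins had a median of -0.38, below the range but inside that of lists not matched on expression, with 3 of 77 members lower, RPL6 (-1.08), RPL7A (-1.07) and RPS7 (-1.01).

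Medians inside the range were found for p53 targets (-0.14), apoptosis regulators (0.43), ribosome biogenesis and MYC targets (-0.20), oxidative phosphorylation (0.14), glycolysis and hypoxia (0.28), cholesterol synthesis (-0.23) and the cytoskeleton (0.32). Within these, GADD45A (3.25), BBC3 (2.21), PMAIP1 (2.03), BNIP3L (2.51), MSMO1 (1.77) and TUBA4A (6.27) were higher, and CAD (-2.93), FBL (-1.92) and STMN1 (-2.26) lower. MT1F was lower (-1.66), while MT2A (0.27) and MT1X (0.70) were within 2-fold. Among genes with at least 50 CPM in either library, the highest after FGB were MLLT11 (7.04), TUBA4A, GPX3 (6.13), RASD1 (5.58), KRT81 (5.53), HSPB8, RGCC (5.16), GLRX (5.15) and the deubiquitinase gene UCHL1 (5.11). The lowest of them were MYBL2 (-8.73), MKI67, BIRC5, RRM2, IGFBP5 (-6.99), RP11-662G23.1 (-6.68), HELLS, KIAA0101 (-6.06), the receptor gene GFRA1 (-5.78) and BRIP1 (-5.68). Median-ratio scaling moved the median log2 fold of all genes by 0.36 and gave 1587 higher and 1155 lower genes, and TMM moved it by 0.25 and gave 1356 and 1361. A total without mitochondrially encoded and ribosomal protein genes moved it by -0.26 and gave 648 and 2818.

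Recovery against 48 h asks what differed after the drug was removed, although exposure before the wash was also longer, by 24 h if the t48 library is of 48 h. Heat shock chaperones were lower at recovery for 16 of 24 members (median -1.24), and HSPA1A had 929 CPM (95% interval 921 to 937) at 48 h and 195 CPM (190.3 to 199.5) at recovery, a log2 fold of -2.25 (-2.29 to -2.22). Interferon response genes were higher for 10 of 15 members (median 2.21), among them OASL (chromosome 12, 121019111 to 121039242), an interferon-induced gene, with 4.02 CPM (95% interval 3.50 to 4.60) at 48 h and 76.6 CPM (73.8 to 79.6) at recovery, a log2 fold of 4.25 (4.05 to 4.46). Estrogen receptor targets (6 of 13 higher) and luminal markers (8 of 18 higher) had medians of 0.88 and 0.87, both above the range. By the rule of size 847 genes were higher and 622 lower among 6663, with a median log2 fold of -0.11.

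IFIT1 (6.84), IFI44 (4.63) and IFIT2 (3.49) were the other interferon genes with the largest folds. In thinned cells, an ISG15 UMI was found in 92.1% of recovery cells (90.5% to 93.6%) and 53.7% of 48 h cells (51.4% to 56.0%), at median depths of 25859 and 25271 UMIs before thinning. An IFIT1 UMI was found in few cells, 3.08% at recovery (2.19% to 4.20%) and 0.108% at 48 h (0.0131% to 0.390%). At 0 h it was found in 1.84% of cells (1.25% to 2.60%). NF-kB targets were higher for 5 of 7 members (median 1.49, above the range), including IL6 (2.92) and NFKBIA (2.19), the inhibitor that NF-kB itself induces. Immediate early genes had a median of 0.60, above the range, with JUNB (2.38) and ZFP36 (2.05) higher and FOSL1 (-2.28) lower. The unfolded protein response list was above the range at 0.52, with XBP1 (3.13), CRELD2 (1.54) and PDIA4 (1.26) higher. AGR2 (3.88), a disulfide isomerase of the endoplasmic reticulum, TPD52L1 (1.89) and CCND1 (1.54) were higher among estrogen receptor targets, and ESR1 was at 1.69 CPM at 48 h and 2.53 CPM at recovery. Luminal markers MUC1 (5.23) and KRT19 (2.30) were higher, as were KRT17 (3.04) and CAV1 (2.65) among basal and mesenchymal markers. Histones were higher for 9 of 16 members (median 1.62, above the range), including HIST1H2BG (3.51) and HIST2H2BE (3.31), while HIST1H4C was lower (-2.72). The cytoskeleton list was above the range at 0.31, with TMSB4X (chromosome X, 12975108 to 12977227) at 1094 CPM (95% interval 1086 to 1103) at 48 h and 12509 CPM (12472 to 12546) at recovery, a log2 fold of 3.51 (3.50 to 3.53). TMSB10 (2.15) and KRT19 were higher in it as well, and its median was -0.036 in cells with at least 10000 UMIs and 2% to 20% mitochondrial UMIs and inside the range under 4 other alternatives. The metallothioneins MT2A (3.76), MT1X (2.60) and MT1F (1.35) were higher. The G1 list was above the range at 0.79, but inside it in those cells and with a total without mitochondrially encoded and ribosomal protein genes, with CDKN1A (1.38) and CDKN2B (1.31) higher.

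Lists below the range were proteasome subunits (-0.47, with 1 of 33 lower, PSMD6 at -1.02), the integrated stress response (-0.67, with 9 of 24 lower), S phase (-0.89), G2/M (-0.77) and cytosolic ribosomal proteins (-0.31, inside the range of lists not matched on expression), besides heat shock. SESN2 (-2.53), DDIT3 (-1.71), ATF4 (-1.57), HSPA6 (-3.39), HSPA1B (-2.57), BAG3 (-2.49) and CKS2 (-1.54) were lower. Medians inside the range were those of NRF2 targets (0.01), autophagy (-0.24), p53 targets (0.19), apoptosis (-0.13), proteasome assembly (-0.06), ribosome biogenesis and MYC targets (-0.25), mitochondrially encoded genes (-0.10), oxidative phosphorylation (0.16), glycolysis (0.08) and cholesterol synthesis (0.34). AKR1C1 was lower (-3.25) and FTH1 higher (1.72) among NRF2 targets, BCL2L1 higher (1.48) among apoptosis regulators, and HK2 (1.95) and INSIG1 (1.15) higher in the metabolic lists. Among genes with at least 50 CPM in either library, the other highest were MSMB (5.03), CYP1B1 (4.64), LMTK3 (4.06), RGCC (3.90), SPTSSB (3.77) and PCAT6 (3.46), and the other lowest were EEF1A2 (-4.72), which encodes a translation elongation factor, SNHG12 (-3.45) and CD81 (-2.60). PCAT6 and SNHG12 are annotated as antisense to other genes. Median-ratio scaling moved the median log2 fold of all genes by -0.14 and gave 728 higher and 948 lower genes, and TMM moved it by -0.24 and gave 601 and 1209. A total without mitochondrially encoded and ribosomal protein genes moved it by -0.14 and gave 645 and 883.

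Genes changed against 0 h overlapped between time points. Among genes with enough expression in both comparisons, 648 were higher at both 12 h and 48 h and 969 lower at both, while independent draws would share 124 and 302 and 100 simulations without effects, with the 0 h library shared, gave a mean of 0. Between 48 h and recovery 507 were shared as higher and 1411 as lower, against 96.8 and 572. For 12 h and recovery the counts were 339 and 702, against 86.9 and 304.5, and the simulated mean was 0 for these pairs too. All 3 times shared 314 higher and 675 lower genes. The draws leave out the shared 0 h library and the simulations leave out the effects, so the excess over either is no measure of a shared effect, and part of it may come from the 0 h library.

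The share of UMIs from S phase genes was 0.116% (0.115% to 0.117%) at 0 h, 0.0511% (0.0504% to 0.0518%) at 12 h, 0.0243% (0.0239% to 0.0248%) at 48 h and 0.0149% (0.0145% to 0.0153%) at recovery. For G2/M genes it was 0.258% (0.257% to 0.260%), 0.185% (0.184% to 0.187%), 0.139% (0.138% to 0.140%) and 0.113% (0.112% to 0.114%). On thinned cells, 19.3% (17.4% to 21.2%) of 0 h cells were called G2/M, 7.85% (6.82% to 8.99%) at 12 h, 0.648% (0.335% to 1.13%) at 48 h and 0.810% (0.389% to 1.48%) at recovery. S calls made up 47.9%, 26.5%, 16.3% and 4.86%, and G1 calls 32.9%, 65.7%, 83.0% and 94.3%. Many of the calls lay within 0.05 of the limit between calls. For G1 these were 313 of 555 cells at 0 h, 1116 of 1622 at 12 h, 1097 of 1537 at 48 h and 534 of 1165 at recovery. For S they were 183 of 808, 459 of 654, 260 of 302 and 59 of 60 in that order, so most S calls of the treated libraries were borderline. For G2/M they were 47 of 325, 129 of 194, 12 of 12 and 6 of 10. Phase calls cannot separate cycling cells from cells that hold free RNA of others, which was not measured. An MKI67 UMI was found in 28.97% of thinned 0 h cells (26.8% to 31.2%), 7.94% at 12 h (6.90% to 9.07%), 2.76% at 48 h (2.06% to 3.61%) and 0.162% at recovery (0.0196% to 0.584%).

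The stress lists differed in most cells at 12 h. The median share of a cell's UMIs from heat shock chaperones was 0.467% at 0 h, 2.1% at 12 h, 1.75% at 48 h and 0.567% at recovery. Above the 99th percentile of the 0 h cells lay 87.2% (85.8% to 88.5%), 67.2% (65.0% to 69.3%) and 9.39% (7.82% to 11.2%) of the treated cells in that order. For proteasome subunits these were 56.2% (54.3% to 58.2%), 77.4% (75.4% to 79.3%) and 22.6% (20.3% to 25.03%). Integrated stress response genes gave 72.2% (70.4% to 73.9%), 10.7% (9.33% to 12.2%) and 10.1% (8.50% to 11.9%). The interferon list gave 0.202% (0.0658% to 0.472%), 0.324% (0.119% to 0.704%) and 10.7% (9.02% to 12.5%). Its median share was 0.05% at 0 h, 0.05% at 12 h, 0.0667% at 48 h and 0.15% at recovery. For G2/M genes 1 cell at 12 h lay above that percentile, 0 of 1851 at 48 h and 0 of 1235 at recovery, which allows up to 0.199% and 0.298%. The median G2/M share of a cell's UMIs changed less, at 0.167% at 0 h, 0.167% at 12 h, 0.133% at 48 h and 0.1% at recovery.

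**Figure D3:**
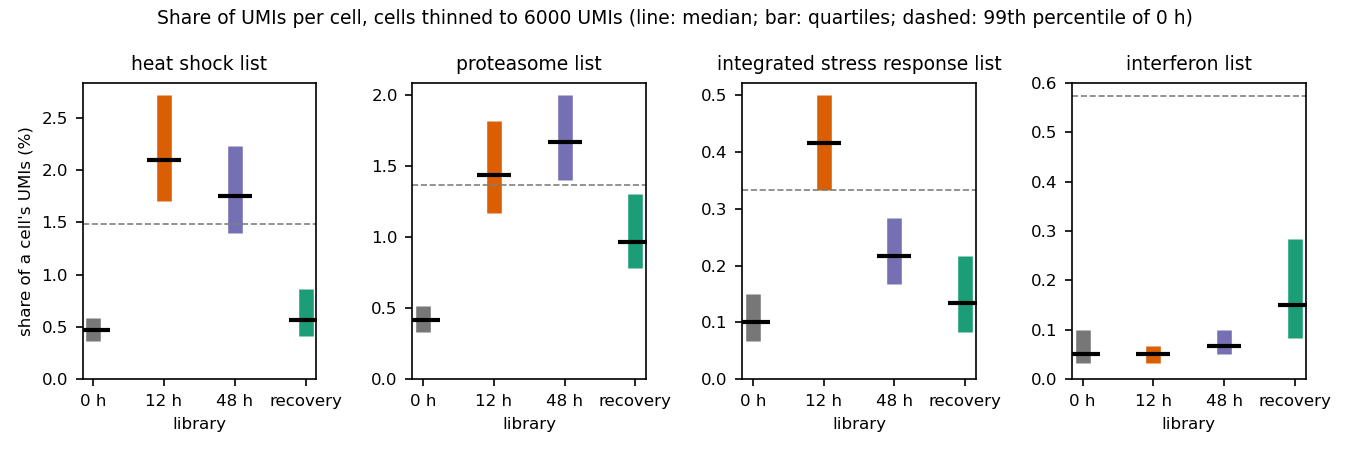
Share of each cell's UMIs from 4 gene lists in percent (vertical axis) in the 4 libraries, after thinning to 6000 UMIs, with the median as a line, the quartiles as a bar and the 99th percentile of the 0 h cells as a dashed line. The heat shock median is 2.1% at 12 h and 0.567% at recovery, and the interferon median 0.05% at 12 h and 0.15% at recovery.

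Cells clustered by time point. Of 10 clusters, 3 were made mostly of 0 h cells, and their leading genes included TOP2A and MKI67 in the largest and IGFBP5, CALML5 and LINC00052 in the next. The smallest of them, led by CDC20, PTTG1 and CCNB2, was mixed, with 31 cells of 0 h and 25 of 12 h. Of the clusters of 12 h cells, the largest, 1318 cells, was led by DDIT4, SNHG15 and SHMT2, and one of 298 cells by ASNS, SLC3A2 and PHGDH. The latter had low median UMIs, 11162, and the highest median mitochondrial share of all clusters, 8.28%. A cluster of 1516 cells, 1510 of them from 48 h, was led by AKR1C1, EEF1A2 and TUBA4A, and one of 1236 cells, 1228 of them from recovery, by OASL, MSMB and FGB. Clusters of 793 cells, mostly of 12 h, and of 337 cells, mostly of 48 h, were both led by LRRC75A and had low median UMIs, 8551 and 14144. Cells in clusters made mostly of another library numbered 12 of 1726 at 0 h (0.695%, 0.360% to 1.21%), 29 of 2743 at 12 h (1.06%, 0.709% to 1.51%), 6 of 1851 at 48 h (0.324%, 0.119% to 0.704%) and 7 of 1235 at recovery (0.567%, 0.228% to 1.16%). With 1 library per time point, a cluster of 1 time point and a cluster of 1 library are the same thing. The median distance between pairs of cells was 0.330 at 0 h, 0.369 at 12 h, 0.344 at 48 h and 0.362 at recovery. Relative to 0 h these were 1.12, 1.04 and 1.10, and in 20 further draws of cells the ratios ran from 1.11 to 1.14, 1.01 to 1.04 and 1.07 to 1.09, so the values of the first draw at 48 h and recovery were above all of them. With Spearman correlation the ratio fell below 1 at 48 h (0.969) and recovery (0.964), and in unthinned cells at 48 h (0.895).

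Folds also differed by the length of the mRNA. Genes with mRNAs over 4000 nt had a median log2 fold against 0 h of -0.08 at 12 h, -0.66 at 48 h and -0.98 at recovery, whereas genes of 1200 to 2000 nt had 0.23, 0.10 and 0.11. At 12 h the shortest mRNAs, up to 600 nt and 600 to 800 nt, had the lowest medians, -0.46 and -0.11, with 21.6% and 16.96% of genes lower. Of the genes over 4000 nt, 8.22% were higher and 15.2% lower at 12 h, 6.74% and 37.7% at 48 h, and 5.27% and 49.0% at recovery. Over all genes the shares were 13.7% and 14.0% at 12 h, 13.4% and 26.9% at 48 h, and 12.1% and 26.5% at recovery. All of these levels move with the scaling, by 0.50 at 48 h and 0.36 at recovery with median ratios, but the gap between lengths does not, since 1 factor applies to all genes of a library. ESR1 and MKI67 are among the genes with long mRNAs that were lower at 48 h and recovery.

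**Figure D4:**
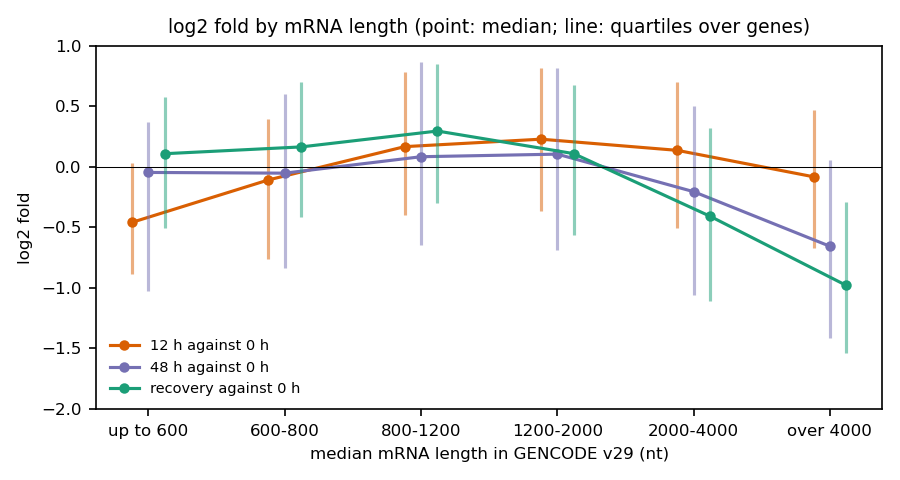
log2 fold against 0 h (vertical axis) of genes binned by the median length of their mRNAs in nt (horizontal axis), with the median as a point and the quartiles over genes as a line, for 12 h, 48 h and recovery. In the bin over 4000 nt the medians are -0.08, -0.66 and -0.98.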

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

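Cells with at least 10000 UMIs and 2% to 20% mitochondrial UMIs, and genes with mRNAs of 800 to 2000 nt, were alternatives chosen after the data were seen, and the others were chosen before. Of 400 medians of the leading lists under alternatives, 391 kept their call as inside or outside the central range, as did 809 of 860 medians of the other lists. Median-ratio, TMM and the total without mitochondrially encoded and ribosomal protein genes scale all genes of a library alike. Under these a list and its random lists shift together. Calls could then change only through genes crossing the minimum CPM or through new random draws, so these settings hardly test the calls. A change of direction was counted only for medians outside the range in the main analysis, so those inside it may have changed sign. Of 150 counts of genes, 88 stayed within 1.5 times the main count and 62 did not. Of 8877 values of named genes, 8084 kept their call, 584 fell short of the rule, 207 newly met it and 2 changed direction. Of 51 results on cells, 26 stayed within their interval, 22 moved and 3 changed direction. The lack of replicates limits all comparisons, as does the lack of untreated cells at the later times.

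With median-ratio size factors the counts were 1232 higher and 859 lower for 12 h against 0 h, 2069 higher and 1104 lower for 48 h against 0 h, 1587 higher and 1155 lower for recovery against 0 h, 711 higher and 342 lower for 48 h against 12 h and 728 higher and 948 lower for recovery against 48 h, and with TMM 1354 higher and 820 lower for 12 h against 0 h, 2051 higher and 1127 lower for 48 h against 0 h, 1356 higher and 1361 lower for recovery against 0 h, 616 higher and 404 lower for 48 h against 12 h and 601 higher and 1209 lower for recovery against 48 h. The 48 h median of cytosolic ribosomal proteins became 0.44 with median-ratio scaling and 0.43 with TMM, because the reference level itself moved. Without a minimum CPM there were 1915 higher and 3372 lower for 12 h against 0 h, 1804 higher and 5958 lower for 48 h against 0 h, 2459 higher and 4776 lower for recovery against 0 h, 696 higher and 3497 lower for 48 h against 12 h and 3558 higher and 1394 lower for recovery against 48 h. With a minimum of 50 CPM there were 540 higher and 296 lower for 12 h against 0 h, 589 higher and 489 lower for 48 h against 0 h, 473 higher and 433 lower for recovery against 0 h, 104 higher and 253 lower for 48 h against 12 h and 276 higher and 211 lower for recovery against 48 h. A limit of 1.5-fold gave 2168 higher and 1917 lower for 12 h against 0 h, 1800 higher and 2972 lower for 48 h against 0 h, 1672 higher and 3070 lower for recovery against 0 h, 660 higher and 2284 lower for 48 h against 12 h and 1459 higher and 1670 lower for recovery against 48 h, and one of 4-fold gave 185 higher and 245 lower for 12 h against 0 h, 238 higher and 821 lower for 48 h against 0 h, 289 higher and 600 lower for recovery against 0 h, 33 higher and 119 lower for 48 h against 12 h and 232 higher and 35 lower for recovery against 48 h. Genes with mRNAs of 800 to 2000 nt gave 453 higher and 259 lower for 12 h against 0 h, 494 higher and 456 lower for 48 h against 0 h, 430 higher and 333 lower for recovery against 0 h, 90 higher and 238 lower for 48 h against 12 h and 310 higher and 146 lower for recovery against 48 h. The minimum, the limit on the fold and the length range change the number of called genes by construction, but not their split. For 48 h against 0 h, 33.2% were higher in the main analysis, 23.2% without a minimum, 54.6% with 50 CPM and 52.0% in the length range. For recovery against 0 h these shares were 31.3%, 34.0%, 52.2% and 56.4%. For recovery against 48 h, 57.7% were higher in the main analysis, 46.6% at 1.5-fold and 86.9% at 4-fold. The cause of these shifts was not tested.

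In cells called G1 alone, 729 genes were lower at 12 h, and the 12 h medians became 0.036 for S phase, 0.39 for G2/M and 0.13 for cyclins, kinases and inhibitors of G1, with MKI67 at 0.011 and OASL at 0.18. At 48 h against 0 h the S phase median was -0.40 and the G2/M median -0.18, and against 12 h the S phase median was -0.39, all inside the range. Choosing G1 cells removes cells high in the S and G2/M lists by construction, and for OASL the cause was not tested. The heat shock median at recovery against 0 h became 0.82 in these cells, above the range. Against random lists not matched on expression, its main value of 0.55 was above the range, and that of 48 h against 12 h, -0.52, was inside it. In cells with at least 10000 UMIs and 2% to 20% mitochondrial UMIs, the interferon median of recovery against 0 h was -0.090, with members chosen again in those cells, and the cytoskeleton median of recovery against 48 h was -0.036. Further list calls ended inside the range: for 12 h against 0 h the G1 list with median-ratio and TMM scaling and equal weight per cell, and for recovery against 48 h the G1 list in the same 10000-UMI cells and with a total without mitochondrially encoded and ribosomal protein genes. The cytoskeleton list of that comparison did so with equal weight per cell, without the top 5% of cells, in G1 cells and against lists not matched on expression. Against such lists, mitochondrially encoded genes at 48 h against 0 h and 12 h, and cytosolic ribosomal proteins at 48 h and recovery against 0 h and at recovery against 48 h, were inside the range too. Medians inside the range lay outside it under at least 1 alternative for apoptosis regulators, ribosomal proteins and MYC targets at 12 h, for apoptosis regulators, immediate early genes, basal markers and the G1 list at 48 h, and for luminal markers, apoptosis regulators and the cytoskeleton at recovery, all against 0 h. The same held for autophagy and ribosomal proteins for 48 h against 12 h and for cholesterol synthesis for recovery against 48 h. For the changes in this paragraph, other than those from choosing G1 cells, the cause was not tested, except that with the members held fixed the interferon median was 0.22.

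In unthinned cells, S calls were 31.8% at 12 h, 10.8% at 48 h and 2.75% at recovery, G2/M calls 4.01%, 0.108% and 0.324%, and G1 calls 89.1% at 48 h and 96.9% at recovery. Leiden resolution 0.25 gave 5 clusters, and resolution 1 put 1.24% of 48 h cells in clusters of another library. The distance ratio to 0 h at 12 h was 1.19 with 500 genes, 1.04 with Spearman correlation, 1.27 in unthinned cells and 1.18 in G1 cells. At 48 h it was 1.16, 0.969, 0.895 and 1.09, and at recovery 1.36, 0.964, 1.11 and 1.13. The direction therefore depended on the measure at 48 h and at recovery, and the cause was not tested. In 20 further draws of cells the 0 h distance ran from 0.3299 to 0.337 and the 48 h distance from 0.339 to 0.3437, and the first draw, with 0.330 and 0.344, lay near the bottom of the former and above all of the latter. The ratio had a median of 1.03 over those draws at 48 h (1.01 to 1.04) and 1.08 at recovery (1.07 to 1.09), under the first draw's 1.04 and 1.10. Unthinned cells above the 99th percentile of 0 h were 58.4% at 12 h and 81.5% at 48 h for the proteasome list, and 84.9% at 12 h for the integrated stress response list. Alternatives for normalized values and for cells without library names were not run, since the table holds counts and names each cell's library.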

Other observations

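The tests on barcodes, mitosis and free RNA in the 12 h cells that grouped with 0 h cells, and those on connective tissue, endothelial and blood cells, were chosen after the result was seen. The test of mitosis was chosen once the leading genes of the cluster were known, and those on other cell types replace earlier forms on summed levels, which were undecided or rested almost wholly on COL1A1. The remaining tests were written before their values were seen, on patterns already seen in these libraries.

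Markers of other cell types were mostly low. Of the blood cell list, 9 of 18 genes were in the table, and their summed level was 5.62, 11.0, 17.0 and 38.7 CPM from 0 h to recovery. CD68, a lysosomal protein of macrophages that other cells express too, made up most of the later sums, with 1.22, 2.96, 13.6 and 32.6 CPM. EGFL7, a gene of endothelial cells, made up most of the fibroblast and endothelial sums of 83.9, 195.7, 225.3 and 150.3 CPM, with 81.4, 192, 222 and 147 CPM. COL1A1 was at 1.75 to 3.17 CPM in the 4 libraries. Basal and mesenchymal markers summed to 113.0, 65.2, 75.7 and 147.0 CPM, and KRT6A was highest at 48 h, at 26.4 CPM, while KRT17 was highest at recovery, at 59.1 CPM. The actin-binding genes TMSB4X and TMSB10 were lower at 12 h and 48 h than at 0 h or recovery: TMSB4X was at 7489, 1037, 1094 and 12509 CPM, and TMSB10 at 5796, 525, 1098 and 4858 CPM. MT2A followed a like course, at 1050.2, 175, 93.6 and 1264 CPM.

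At 48 h and at recovery, genes with mRNAs over 4000 nt had lower median log2 folds against 0 h than genes of 800 to 2000 nt. The gap between the medians was -0.75 and -1.14. The tests argue against 3 explanations as the whole cause: in cells with at least 10000 UMIs and 2% to 20% mitochondrial UMIs 103% of the gap at 48 h and 91.0% at recovery remained, within 10 groups of genes by GC content 113% and 104%, and in G1 cells without cell cycle and histone genes 98.1% and 99.8%. Separate library preparation at each time point stays open, since each time point has 1 library. A biological difference between long and short transcripts under the drug stays open too and was not tested. None of the tests matched genes on expression level, as was done for the gene lists, so its part in the gap was not tested either. The pattern may bear on long genes such as ESR1 and MKI67, whose folds of -5.66 and -4.21 at 48 h are far beyond the gap.

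Interferon response genes were higher at recovery than at 48 h, with a median log2 fold of 2.21. Without the 5% of cells with the largest share of the list 102% of that median remained, and in cells with at least 10000 UMIs and 2% to 20% mitochondrial UMIs 106%, which argues against a few cells and against damaged cells as the whole cause. Even so, the 5% of recovery cells with the most UMIs of the list held 37.1% of its UMIs. Those cells were ranked by number of UMIs and not by share, so they are not the set left out above. Of the 546 recovery cells above the 95th percentile of 48 h in the list, 44.2% of the thinned recovery cells, 7.88% (5.76% to 10.5%) held a UMI of the fibroblast genes COL1A1, COL3A1 and PDGFRA, 1.83% (0.882% to 3.34%) one of the endothelial genes PECAM1, VWF, CDH5 and KDR and 12.8% (10.1% to 15.9%) one of the blood cell list without CD68, as did 6.97%, 0.871% and 13.9% of the others, which argues against connective tissue, endothelial and blood cells as the whole cause. COL1A1 made up nearly all of the fibroblast level, and between 48 h and recovery the summed levels went from 3.17 to 2.73 CPM for fibroblast, 0.0949 to 0.455 CPM for endothelial and 3.40 to 6.03 CPM for blood cell genes. Separate library preparation stays open, as do drug removal, the longer exposure and the longer time in culture, which were not tested.

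Of the 12 h cells, 28 grouped with cells of 0 h, none of them (0) with a barcode of a 0 h cell, which argues against carried-over barcodes. Of the 28, 25 were in a mixed cluster of 31 cells of 0 h and 25 of 12 h. That cluster counts as one of 0 h only by this small majority. With all cells thinned to 6000 UMIs, 86.4% (19 of 22) still grouped with 0 h cells, which argues against shallow counts for those 22. The rest of the 28 had fewer than 6000 UMIs and were left out of that test. Median UMIs were 14978 in the other 12 h cells and 12384.5 in the 28. Their proteasome and heat shock lists covered 111% and 83.7% of the way from the 0 h to the 12 h level, 27.7 percentage points apart, which argues against untreated cells with free RNA of 1 source, while the integrated stress response list covered 33.0%, HSPA1A 52.0% and the estrogen receptor targets -60.5%, so they resembled the other 12 h cells in part. With cells clustered without the S and G2/M list genes, 77.3% of the 12 h cells in clusters of mostly 0 h cells, 17 of 22 thinned cells, were called G2/M, while 7.85% of all thinned 12 h cells were. CDC20, which acts in mitosis, was at 344 CPM in the 28 cells, 37.9 at 0 h and 5.10 in the other 12 h cells. It is in the G2/M list and leads a cluster that holds 25 of the 28, so its level is no separate support. CCNB1 and PLK1, mitotic genes chosen after their values were seen, were at 626 and 164 CPM in the 28 cells against 58.4 and 3.90 in the other 12 h cells. A candidate explanation is that these cells were in mitosis under the drug, a hypothesis found and tested on the same data.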
